A study of Mus musculus with 12 samples.

How the data were processed

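The 12 libraries came from mouse limb buds at embryonic day 12.5, the stage at which limb cartilage condenses. Per the labels, 6 came from limb buds with a conditional knockout of Mettl14 (cKO) and 6 from heterozygous controls with 1 wild-type and 1 floxed allele (cHet). Mettl14 encodes a subunit of the enzyme complex that writes N6-methyladenosine (m6A) on RNA. From each cytoplasmic lysate, RNA was sequenced before (input) and after sucrose gradient ultracentrifugation that isolates polysomes, the mRNAs carrying several ribosomes (polysome). This gives 4 groups of 3 biological replicates, as the labels call them. RNA was extracted with the Quick RNA Microprep kit and libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols. Neither ribosomal RNA depletion, poly(A) selection nor strandedness is given in the sources used here, so reads from a gene and an antisense partner cannot be told apart.

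HISAT2 2.0.5, a read aligner, and featureCounts 1.5.0-p3, a read counter, were used with the mm10 build, per the submitters' processing notes. The authors deposited a table of FPKM values (fragments per kilobase of gene model, scaled to the same number of assigned reads in each library) for 54532 genes, of which 22046 were protein-coding, with gene lengths and coordinates. FPKM is already scaled by depth and gene length, so a gene's value also depends on what the rest of its library holds. Multiplying each FPKM by gene length returned whole reads within a tolerance of 0.01 for 100% of the values above 0, which gives the depth of each library. The libraries held 10349912 to 30068823 assigned reads. These sums were 94.9% to 102% of the total each library's FPKM values imply. A single read in a gene of 1 kb was worth 0.0320 FPKM in the deepest library and 0.0930 FPKM in the shallowest. Each library counts as 1 sample, by the design.

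Values were analysed as log2(FPKM + 0.1) with limma 3.58.1 in R 4.3.3, with an intensity trend in its empirical Bayes step. Fold changes are on this scale, which understates the change of low genes. A gene was tested if it reached an FPKM of 1 in at least 3 of the fitted libraries. The genotypes were compared within input and within polysome RNA, each on 6 libraries. Polysome against input within each genotype, and the difference of those differences between genotypes (the interaction, a change in the polysome to input ratio), were fitted on all 12 libraries with 4 group means. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes are limma's and two-sided. With 3 libraries against 3, an exact permutation test of a single value cannot go below p = 0.1. Design, lists and named genes were set before the data were examined.

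Gene groups were tested with camera from limma, two-sided, at a preset inter-gene correlation of 0.01, on 31 lists of pathways, cell type markers and RNA quality with at least 3 tested members. Camera asks whether a list's genes moved relative to the other genes, and its p-values were adjusted over the lists of a comparison. No camera call in any of the 5 comparisons held when the correlation was estimated from the data, and that adjusted p stands beside each. Members of a list were also adjusted over the list alone.

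The genes named in the text are Mettl14, Gdf5, Runx1, Runx2 and Runx3, which the series title is about. To these come, per comparison, the 10 higher and the 10 lower protein-coding genes with the largest change among those past the threshold whose groups did not overlap and whose mean reached an FPKM of 5 in the higher group. Where none passed, the 5 with the smallest p per direction are named, as not passing. Of each list described, up to 4 members with the smallest p are named. Genes named outside this scheme are said to be.

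Input and polysome libraries with the same genotype and replicate number were read as coming from the same lysate, from the design. Their deviations from the group means correlated at 0.05 to 0.27 (Pearson, across genes). The lysate was added to the model as an alternative, and its value is printed where it changed a call. Other alternatives were other pseudocounts and filters, scaling by median ratios, protein-coding scaling, quantile normalization and voom weights on the recovered reads. Robust empirical Bayes, leaving out each replicate, and an adjusted p with a log2 change of at least 1 were used as well. Protein-coding scaling divided each library by its summed FPKM over protein-coding genes outside the mitochondrial genome, a sum of length-scaled values rather than of reads. Chosen after seeing the data were removal of gene length and GC trends (loess, span 0.5), library quality weights, and leaving out the 2 libraries that stood apart. GC content and exon structures came from the GENCODE M21 annotation on the same build, which held 54495 of the 54532 gene identifiers, 98.2% with the same coordinates. GC content was known for 11534 of the 12977 genes of the input comparison. Genes without a known GC content had the length trend removed but not the GC trend.

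The procedure was tested on simulated libraries with 200 changed genes. The simulated noise was independent between genes and, for a gene, of the same size in every library. Libraries that stand apart and trends shared by many genes were not simulated, so the rates below do not cover them. In the simulated input comparison of 12977 genes it recovered 48% of the 100 genes changed by a log2 of 1 and 80% of those changed by 2, with 5 false calls among 133. For cHet polysome against input (13610 genes) the shares were 59% and 88%, with 11 false calls among 158. The interaction on the same 13610 genes recovered 25% and 69%, with 5 false calls among 99. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining computations.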

Results

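RNA from E12.5 mouse limb buds was sequenced in 12 libraries, 3 for each of 4 groups: cHet input, cHet polysome, cKO input and cKO polysome. Input is the RNA of the cytoplasmic lysate and polysome the RNA of the gradient fractions that carry translating ribosomes. Depth was 30068823, 20571183 and 28637840 assigned reads in cHet input replicates 1 to 3, and 26063921, 23547745 and 17863321 in cKO input. In polysome RNA it was 22045151, 10349912 and 23900880 for cHet, and 21595910, 24783880 and 20094433 for cKO. Mitochondrial RNAs made up 2.87% ± 0.176 of the reads in cHet input and 3.47% ± 1.29 in cKO input (SD, n = 3 each), the latter with 4.85% in replicate 1. On polysomes they made up 0.744% ± 0.337 in cHet and 0.664% ± 0.382 in cKO. Globin RNAs took 1.05% ± 0.544 of cHet input, 0.749% ± 0.322 of cKO input, 1.59% ± 0.542 of cHet polysome and 1.40% ± 0.588 of cKO polysome reads.

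Mettl14 (ENSMUSG00000028114; mm10 chromosome 3, 123368297 to 123386108, minus strand, 11 exons), the floxed gene, had an FPKM of 4.09, 4.03 and 4.04 in cHet input replicates 1 to 3. In the libraries labelled cKO input it had 2.60, 3.32 and 1.26, each below each cHet input library. On polysomes the values were 2.83, 3.07 and 3.02 in cHet, and 2.73, 2.81 and 3.29 in the libraries labelled cKO polysome. The genotype difference was a log2 of −0.83 in input (SE 0.32, adjusted p = 0.295) and −0.02 on polysomes (adjusted p = 0.954), and neither passed the threshold. These values cover the whole gene model. Which exons were deleted is not given in the sources used here, so the cKO polysome labels could not be checked with this gene.

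**Figure D1:**
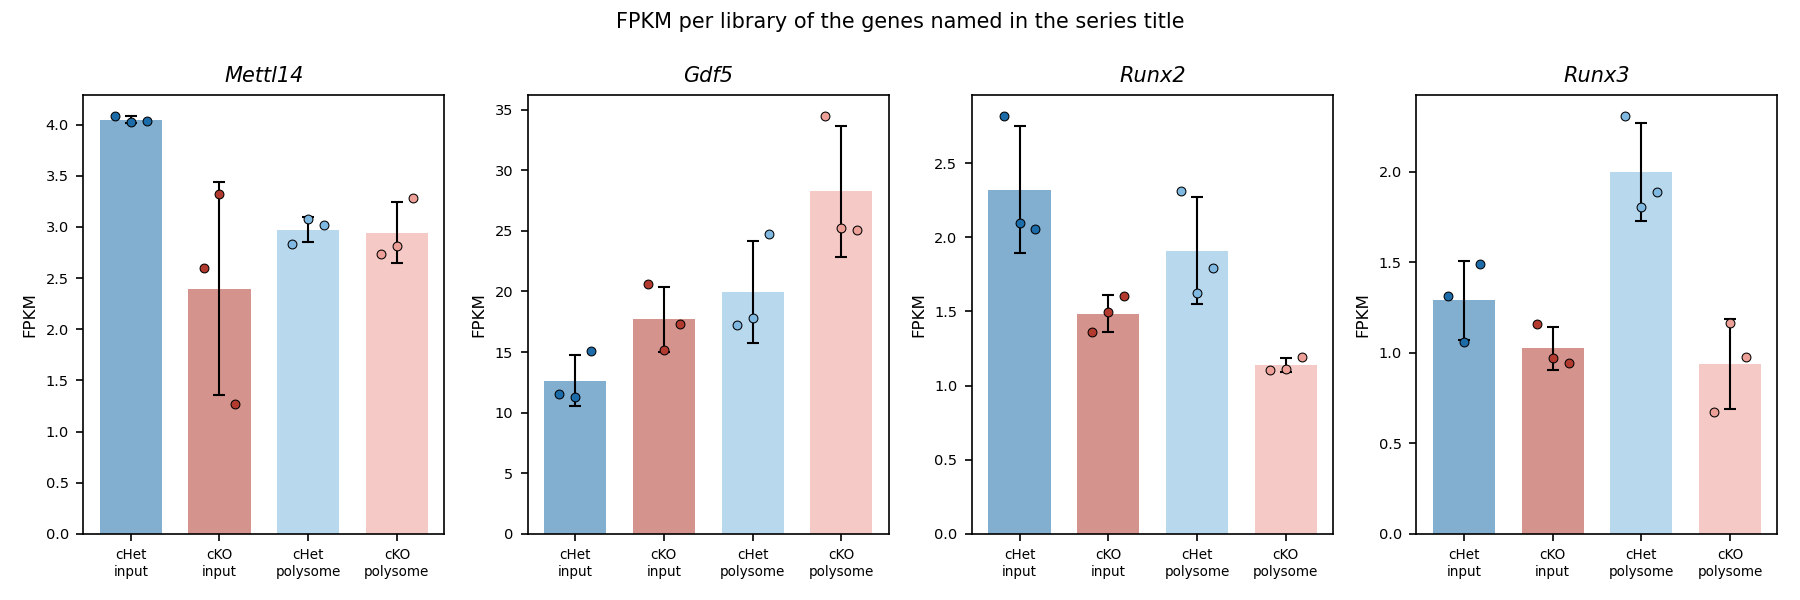
FPKM of Mettl14, Gdf5, Runx2 and Runx3 in each of the 12 libraries, by group, with the group mean and its SD (n = 3). Mettl14 was lower in the 3 cKO input libraries than in the 3 cHet input libraries, while on polysomes the genotypes overlapped at means of 2.97 and 2.94.

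The other genes of the series title encode a growth factor of developing joints and cartilage (Gdf5) and transcription factors of the RUNX family, of which Runx2 and Runx3 act in chondrocyte maturation and bone formation. Gdf5 (ENSMUSG00000038259; mm10 chromosome 2, 155941023 to 155945367, minus strand, 2 exons) averaged 12.7 ± 2.10 FPKM in cHet and 17.7 ± 2.72 in cKO input, and 19.9 ± 4.19 in cHet and 28.3 ± 5.39 on cKO polysomes (SD, n = 3 each). Runx2 (ENSMUSG00000039153; chromosome 17, 44495987 to 44814797, minus strand) averaged 2.32 ± 0.431 in cHet and 1.49 ± 0.122 in cKO input, and 1.91 ± 0.360 and 1.14 ± 0.0475 on polysomes. Runx3 (ENSMUSG00000070691; chromosome 4, 135120652 to 135177990, plus strand) averaged 2.00 ± 0.271 on cHet polysomes against 0.938 ± 0.247 on cKO polysomes, and 1.29 ± 0.217 against 1.03 ± 0.119 in input. The genotype groups did not overlap for Gdf5 and Runx2 in both fractions and for Runx3 on polysomes, a separation that chance gives for 10% of genes with 3 libraries against 3. None of these differences passed the threshold. In input the log2 differences were 0.48 for Gdf5 (SE 0.17, adjusted p = 0.260), −0.60 for Runx2 (SE 0.19, adjusted p = 0.231) and −0.30 for Runx3 (SE 0.21, adjusted p = 0.514). On polysomes they were 0.50 (SE 0.20, adjusted p = 0.199), −0.69 (SE 0.19, adjusted p = 0.128) and −1.04 (SE 0.23, adjusted p = 0.0911). Fitted over all 12 libraries, Runx3 passed on polysomes (adjusted p = 0.0456). Runx1 differed by −0.18 in input and −0.15 on polysomes (adjusted p = 0.690 and 0.688).

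Of the variance over 12875 genes, 55.8% lay on a first principal component that separated input from polysome libraries, and 17.4% on a second. A pair of libraries stood apart from their groups. cKO input replicate 3 had a second-component score of −61.9, where the other input libraries lay between 2.56 and 19.8. cKO polysome replicate 1 had a first-component score of 3.72, where the other polysome libraries lay between 34.5 and 51.6. Counts of changed genes are therefore also given without these libraries, a choice made after seeing the data.

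**Figure D2:**
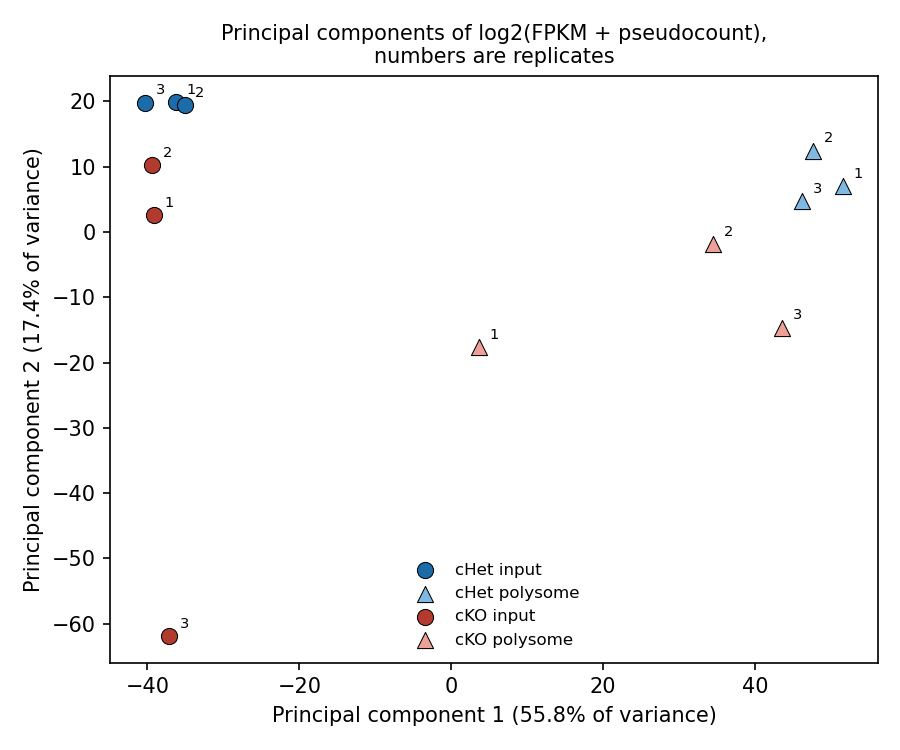
Scores of the 12 libraries on the first (55.8% of the variance) and second (17.4%) principal component of log2(FPKM + 0.1) over 12875 genes, each point a library. cKO input replicate 3 sits at −61.9 on the second component, and cKO polysome replicate 1 at 3.72 on the first, between the input and the other polysome libraries.

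The first comparison asked which cytoplasmic RNAs differed in level between knockout and heterozygous limb buds. In cKO input, limb patterning genes, macrophage markers and epidermis genes were higher, and replication-dependent histone mRNAs and cartilage matrix genes were lower, as groups rather than as single genes. These calls hold at a preset correlation between genes, and with an estimated one none did (adjusted p = 0.702 each). The cartilage call was also lost without any of 3 of the 6 libraries and the epidermis call without either of 2. Inka1 (chromosome 9, 107984223 to 107985879), which encodes an inhibitor of a p21-activated kinase, averaged 39.2 ± 3.31 FPKM in cHet and 117 ± 30.8 in cKO input (SD, n = 3 each; log2 1.55, SE 0.20). Dmrta2, a transcription factor gene best known from the brain, averaged 1.14 ± 0.138 and 4.56 ± 1.20. Lrrc4b, for a synaptic adhesion protein, averaged 5.35 ± 0.0518 and 18.3 ± 5.33. Among lower genes, Col9a2, a collagen of the cartilage matrix, averaged 18.3 ± 2.42 in cHet and 10.5 ± 0.976 in cKO input (log2 −0.79, SE 0.14). Col8a2, another collagen gene, averaged 6.18 ± 0.192 and 3.01 ± 0.686, and Ch25h, for cholesterol 25-hydroxylase, 3.37 ± 0.0775 and 1.77 ± 0.231.

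None of these genes passed the threshold over all genes. By limma, 0 of 12977 genes changed, with a lowest adjusted p of 0.141, which the genes named so far share with Lingo3, Kctd6, Spata18 and Creb3l4. At an unadjusted p under 0.05 there were 1943 genes, and voom called 0 as well, with 1984 at that level. Single libraries decided this count. Without cKO input replicate 3, which stood apart, 326 of 12827 genes changed, 249 higher and 77 lower, and without cKO input replicate 2 it was 47. Leaving out any other library gave 0.

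Among the 326 genes, of the protein-coding ones that reached an FPKM of 5 in the higher group, those that rose most were Lrrc4b (log2 1.55), Tigd2 (1.38), Inka1 (1.37), Med18, Asphd2, Prr7, Kctd6, Rasl11a, Lrfn3 and Pced1b (1.19), at adjusted p from 0.042 to 0.0437. Those that fell most were Col8a2 (−1.12), Papss2 (−1.12), Rsph3a, Otor, Hoxa5, Col9a2 (−0.83), Cthrc1, Efemp1, Rgcc and Slc31a2 (−0.77), at adjusted p from 0.042 to 0.0485. Papss2 makes the sulfate donor for cartilage proteoglycans, and Otor is a gene of cartilage and the inner ear. In the same 5 libraries Mettl14 differed by −0.45 (adjusted p = 0.0768), Gdf5 by 0.49 (adjusted p = 0.115) and Runx2 by −0.65 (adjusted p = 0.0744).

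Gene groups were tested over all their members. Of 29 limb patterning genes tested, 23 were higher in cKO input, with a median log2 of 0.21 (camera adjusted p = 6.84e-04; adjusted p = 0.702 with an estimated correlation). Over all genes 0 of them passed, and adjusted over the list alone 7 were higher. Among these, Lhx2, a mediator of ridge signals to limb mesenchyme, averaged 27.3 ± 2.77 FPKM in cHet and 49.0 ± 6.47 in cKO input. Hoxd13, which specifies digits, averaged 244 ± 40.2 and 390 ± 39.0, and Tbx5, required for the forelimb, 44.1 ± 2.67 and 69.3 ± 11.5. Without cKO input replicate 3, 3 of them rose over all genes (Lhx2, Hand2 and Sall1), and adjusted over the list alone 11 were higher and 1 lower. Over the list alone 2 were higher without cHet input replicate 3 and 0 without cHet input replicate 1 or 2 or cKO input replicate 1. Of 45 replication-dependent histone genes, 40 were lower, with a median of −0.35 (camera adjusted p = 3.86e-06; adjusted p = 0.702 with an estimated correlation). The median was −0.22 without cHet input replicate 2 and −0.53 without cHet input replicate 3. None of these passed over all genes or over the list alone. Hist2h2be averaged 6.48 ± 0.104 and 3.70 ± 0.814. Histone genes are near-identical copies, so the split of reads among them is uncertain.

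Markers of macrophages and epidermis were higher as groups. All 11 macrophage markers tested were higher in cKO input, with a median log2 of 0.42 (camera adjusted p = 3.23e-04; adjusted p = 0.702 with an estimated correlation). For 10 of the 11 the groups did not overlap, which chance gives for 10% of single genes. These markers varied together (estimated correlation 0.333), so they are not independent events. Csf1r, the receptor for macrophage colony-stimulating factor, averaged 3.35 ± 0.516 in cHet and 4.87 ± 0.642 in cKO input, and C1qa, for a complement component, 8.14 ± 1.10 and 12.4 ± 2.65. Of 15 epidermis genes, 13 were higher, with a median of 0.30 (camera adjusted p = 0.0164; adjusted p = 0.702 with an estimated correlation). Among them were the basal keratin genes, with Krt5 at 91.6 ± 2.19 and 119 ± 4.23 and Krt14 at 80.2 ± 3.05 and 105 ± 12.3. In neither list did a member pass over all genes or over the list alone. Without cKO input replicate 3, Krt5 rose over all genes (log2 0.35, adjusted p = 0.0473), and adjusted over the list alone 6 epidermis genes were higher and 1 lower and 5 macrophage genes were higher. The epidermis call was lost without cHet input replicate 3 (median 0.27, adjusted p = 0.0776) or cKO input replicate 3 (0.22, adjusted p = 0.0559), and with length and GC trends removed (0.25, adjusted p = 0.120).

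Cartilage matrix genes and cell cycle genes were lower in cKO input as groups. Of 12 cartilage matrix genes, 9 were lower, with a median log2 of −0.47 (camera adjusted p = 0.0270; adjusted p = 0.702 with an estimated correlation). Col9a2, Matn4 (6.01 ± 1.53 and 3.43 ± 0.0656 FPKM) and Cnmd (2.76 ± 0.548 and 1.61 ± 0.329) passed adjusted over the list alone, and 0 did over all genes. This call was lost without cHet input replicate 3 (median −0.37, adjusted p = 0.0776), cKO input replicate 2 (−0.44, adjusted p = 0.139) or cKO input replicate 3 (−0.29, adjusted p = 0.115). It was also lost with median-ratio scaling (adjusted p = 0.0628), protein-coding scaling (0.0635) and quantile normalization (0.0533), at medians of −0.52, −0.52 and −0.43. Of 25 cell cycle genes, 20 were lower, with a median of −0.21 (camera adjusted p = 0.0270; adjusted p = 0.702 with an estimated correlation). Pcna, the sliding clamp of DNA replication, averaged 116 ± 8.29 and 90.9 ± 10.1, while Birc5, for survivin, averaged 32.9 ± 0.387 and 46.3 ± 7.22. The cell cycle call was lost without cHet input replicate 3 (−0.16, adjusted p = 0.0776) or cKO input replicate 1 (−0.11, adjusted p = 0.247). No cell cycle gene passed over all genes or over the list alone.

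Ribosomal protein mRNAs were higher in cKO input in 70 of 78 cases, with a median log2 of 0.18 (camera adjusted p = 4.56e-04; adjusted p = 0.853 with an estimated correlation). This call was lost without cKO input replicate 3 (0.06, adjusted p = 0.149) and with quantile normalization (0.04, adjusted p = 0.166), and the median was 0.26 without cKO input replicate 2. Rpl29 averaged 367 ± 38.9 and 487 ± 39.0 FPKM. Processed pseudogenes share reads with these genes, so single values are uncertain, and none passed over all genes or over the list alone. Of the genes of GDF5 and BMP signalling, 18 of 28 were higher (median 0.18, camera adjusted p = 0.0654), and the list passed without cKO input replicate 3 (median 0.18, adjusted p = 0.00755; adjusted p = 0.717 with an estimated correlation). Over all genes 0 of them passed, and adjusted over the list alone 3 were higher, namely Msx2, a target of BMP signalling in the limb (23.9 ± 2.54 and 52.6 ± 8.98), the inhibitor gene Smad7 (7.27 ± 0.463 and 13.4 ± 3.43) and the receptor gene Acvr2b (log2 0.88, SE 0.22). Without that library Msx2 and Smad7 rose over all genes, and over the list alone 4 were higher and 2 lower. Groups that passed only without it were nuclear genes of oxidative phosphorylation, which were lower (median −0.13, adjusted p = 6.23e-04), mitochondrially encoded genes, which were higher (0.47, adjusted p = 0.00655), and endothelium genes, which were lower (−0.16, adjusted p = 0.0333), each at adjusted p = 0.710 with an estimated correlation. Single oxidative phosphorylation genes went both ways there. Of 92 tested, 3 rose and 1 fell over all genes, and over the list alone 4 were higher and 7 lower. No mitochondrially encoded or endothelium gene passed by either count. The chondrogenic transcription factors (12 tested, median −0.13, camera adjusted p = 0.296) and joint interzone genes (13 tested, median 0.17, camera adjusted p = 0.776) did not pass.

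The same question was then put to polysome-bound RNA. On cKO polysomes, histone, ribosomal protein and respiratory chain mRNAs were lower, and epidermal, macrophage, collagen and cell cycle mRNAs and those of the m6A machinery were higher, again as groups. With an estimated correlation none of these calls held (adjusted p = 0.834 each), and without cKO polysome replicate 1 those of the respiratory chain (adjusted p = 0.236), collagen (0.411) and cell cycle (0.139) were lost at the preset one too. Hist2h2be averaged 10.4 ± 0.496 FPKM on cHet and 4.55 ± 0.957 on cKO polysomes (SD, n = 3 each; log2 −1.19, SE 0.17). Rbm15 (chromosome 3, 107325421 to 107333673), a subunit of the m6A writer complex, averaged 2.87 ± 0.103 on cHet and 7.39 ± 1.31 on cKO polysomes (log2 1.32, SE 0.16). Tigd2, a gene derived from a transposase, averaged 5.83 ± 0.473 and 13.7 ± 1.21, and Fkbpl, for an immunophilin-like protein, 7.12 ± 0.847 and 18.3 ± 3.24. Thy1, a cell surface glycoprotein gene, averaged 2.14 ± 0.182 and 0.952 ± 0.0229.

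By limma, 0 of 12877 genes changed on polysomes, with a lowest adjusted p of 0.0780 that the 5 genes named share with Lrrn3, Lrrc4b, Hist1h2bl, Ooep and Creb3l4. At an unadjusted p under 0.05 there were 2743 genes, and voom called 0, with 2830 at that level. Without cKO polysome replicate 1, which stood apart, 160 of 12738 genes changed, 100 higher and 60 lower. Without cKO polysome replicate 2 it was 231, without cHet polysome replicate 1 it was 1, and without any other library 0. Among the protein-coding genes of these 160 that reached an FPKM of 5 in the higher group, Lingo3 (log2 2.49), Prr7 (1.40), Lrrc4b, Fkbpl, Inka1, Vasn, Tigd2, Cdh11, Tmem132c and Rbm15 (1.23) rose most, and Cbln4 (−1.27), Gng3, Hist1h2bl, Nqo1, Hist2h2be, Stk32b, Hist1h2bj, Mmab, Hist1h3h and Otor (−0.86) fell most, at adjusted p from 0.0398 to 0.0487. In the same 5 libraries Runx3 differed by −0.84 (adjusted p = 0.0676), Runx2 by −0.67 (adjusted p = 0.120) and Gdf5 by 0.35 (adjusted p = 0.281).

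Of 51 replication-dependent histone genes, 45 were lower on cKO polysomes, with a median log2 of −0.55 (camera adjusted p = 1.16e-12; adjusted p = 0.834 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 21 were lower. Hist1h3h, for instance, averaged 24.9 ± 3.48 and 11.5 ± 3.44 FPKM. Without cKO polysome replicate 1, 5 of the histone genes fell over all genes (Hist1h3h, Hist1h2bj, Hist2h2be, Hist1h2bl and Hist3h2a), and the list median was −0.42. Of 78 ribosomal protein genes, 67 were lower, with a median of −0.27 (camera adjusted p = 1.78e-06; adjusted p = 0.834 with an estimated correlation). Of 94 nuclear genes of oxidative phosphorylation, 67 were lower, with a median of −0.18 (camera adjusted p = 0.00336; adjusted p = 0.834 with an estimated correlation). Without cKO polysome replicate 1 the ribosomal protein median was −0.14 (adjusted p = 0.00360) and the oxidative phosphorylation call was lost (−0.05, adjusted p = 0.236), while without cKO polysome replicate 3 the latter median was −0.30. In both lists 0 members passed over all genes or over the list alone.

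The m6A machinery, which holds writers, readers and erasers of the mark, had 13 of 18 members higher on cKO polysomes, with a median log2 of 0.31 (camera adjusted p = 0.00336; adjusted p = 0.834 with an estimated correlation). Over all genes 0 passed and adjusted over the list alone 4 were higher. Ythdf2, a reader that promotes mRNA decay, averaged 14.7 ± 0.809 FPKM on cHet and 25.3 ± 4.20 on cKO polysomes, and 20.5 ± 0.447 and 30.2 ± 3.88 in input. Ythdf1, a related reader, averaged 46.7 ± 8.85 and 76.1 ± 11.3 on polysomes, and 41.6 ± 0.366 and 65.0 ± 7.66 in input. In input 7 of the 18 members were higher (median −0.09, camera adjusted p = 0.989), 0 passed over all genes and 3 adjusted over the list alone. Without cKO input replicate 3, 4 of them rose over all genes (Ythdf1, Ythdf2, Cbll1 and Rbm15), adjusted over the list alone 7 were higher and 2 lower, and the median was 0.04 (camera adjusted p = 0.166). Without the library that stood apart in each fraction, Ythdf2 and Rbm15 rose in both, by 0.62 and 1.05 in input and by 0.64 and 1.23 on polysomes.

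Epidermis and macrophage markers were again higher in cKO. Of 15 epidermis genes 14 were higher on cKO polysomes, with a median log2 of 0.57 (camera adjusted p = 4.45e-05; adjusted p = 0.834 with an estimated correlation), 0 past the threshold over all genes and 4 adjusted over the list alone. Krt14 averaged 46.7 ± 2.52 and 80.7 ± 27.4 FPKM, and Fgf8, the growth factor of the apical ridge, 4.49 ± 0.945 and 7.45 ± 1.74. All 11 macrophage markers were higher, with a median of 0.59 (camera adjusted p = 6.58e-04; adjusted p = 0.834 with an estimated correlation), 0 past the threshold over all genes and 5 adjusted over the list alone. Without cKO polysome replicate 1 these 5 became 0 (list median 0.40, camera adjusted p = 0.0109), and they were 0 as well without cKO polysome replicate 3 or cHet polysome replicate 1 or 2. Adgre1, which encodes F4/80, averaged 0.680 ± 0.0940 and 1.49 ± 0.398. The genes of GDF5 and BMP signalling did not pass as a group (21 of 27 higher, median 0.10, camera adjusted p = 0.214). Over all genes 0 of them passed, and adjusted over the list alone the same 3 as in input were higher, with Smad7 at 7.38 ± 0.753 and 10.5 ± 0.287.

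Limb patterning genes passed only without cKO polysome replicate 1 (median 0.23, adjusted p = 0.0175; adjusted p = 0.836 with an estimated correlation). The remaining groups past the camera threshold on polysomes each had 0 members past the threshold over all genes. Of 25 cell cycle genes 21 were higher (median log2 0.26, adjusted p = 0.0154; adjusted p = 0.834 with an estimated correlation), and without cKO polysome replicate 1 the call was lost (0.15, adjusted p = 0.139). Of 23 collagens 20 were higher (median 0.45, adjusted p = 0.0192; adjusted p = 0.834 with an estimated correlation), a call also lost without that library (0.16, adjusted p = 0.411). Col18a1, a basement membrane collagen gene, averaged 6.11 ± 0.131 and 13.6 ± 8.42 FPKM. All 7 Schwann and neural crest genes were higher (median 0.44, adjusted p = 0.0257; adjusted p = 0.834 with an estimated correlation), which did not hold without cKO polysome replicate 1 (0.24, adjusted p = 0.159) or cHet polysome replicate 2 (0.32, adjusted p = 0.107). All 4 nuclear-retained RNAs were lower (median −0.66, adjusted p = 0.0192; adjusted p = 0.834 with an estimated correlation), which did not hold without cKO polysome replicate 1 (−0.45, adjusted p = 0.0577) or replicate 3 (−0.70, adjusted p = 0.0607). Of 25 WNT pathway genes 18 were higher (median 0.31, adjusted p = 0.0478; adjusted p = 0.834 with an estimated correlation). That call was lost without any of the libraries except cHet polysome replicate 3, at adjusted p of 0.0505 without cHet replicate 1 and also without cKO replicate 3, 0.107 without cHet replicate 2, 0.139 without cKO replicate 1 and 0.0701 without cKO replicate 2. Adjusted over the list alone, 2 nuclear-retained RNAs were lower, 4 WNT pathway genes were higher and 1 lower, and no cell cycle, collagen or Schwann and neural crest gene passed. The list of Y-linked genes and Xist did not pass camera (3 tested, median 0.95, adjusted p = 0.654). Adjusted over that list alone, 2 were higher and 1 lower on cKO polysomes, and 0 passed in input. Without cKO polysome replicate 1 it was 1 higher and 0 lower. The models held no term for the sex of the embryos, and an unequal mix of sexes was not tested. With length and GC trends removed, the polysome calls of WNT pathway (adjusted p = 0.144), Schwann and neural crest (0.0521), oxidative phosphorylation (0.130) and collagen genes (0.109) were lost.

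With all libraries no gene changed in both fractions, since 0 passed in either by limma. Without the library that stood apart in each, 62 genes rose in both input and polysome RNA and 13 fell in both, among 12240 genes tested in both, and 0 moved in opposite directions. Independent lists of the same sizes (247 and 98 higher, 76 and 57 lower) would share 1.98 and 0.354 genes. The fractions came from the same lysates, so the lists are not independent and no p is given. Genes that rose in both included Inka1, Lrrc4b, Dmrta2 (log2 1.69 in input and 2.21 on polysomes), Msx2 (1.11 and 1.04) and Bambi (1.07 and 0.98). Bambi is a pseudoreceptor that dampens BMP signalling. Genes that fell in both included Cthrc1 (−0.79 and −0.73), Bcl2 (−0.65 and −0.80), an inhibitor of apoptosis, Otor (−0.89 and −0.86) and Creb3l4 (−0.89 and −1.07). Those among them that were not named before were picked after their values were seen.

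In control limb buds, polysome RNA was compared with input to find which RNAs were over- or under-represented on polysomes. Respiratory chain and histone mRNAs were enriched on cHet polysomes. Mitochondrially encoded RNAs, collagens, translation factors and cell cycle genes were depleted. As groups these passed at a preset correlation between genes, and none with an estimated one (lowest adjusted p = 0.372). Ndufb3 (chromosome 1, 58586384 to 58595964), for a subunit of respiratory complex I, rose from 52.8 ± 1.64 FPKM in input to 150 ± 9.02 on polysomes (SD, n = 3 each; log2 1.5, SE 0.14, adjusted p = 7.71e-05). The mitochondrial RNA mt-Co3, translated on mitochondrial ribosomes, fell from 119 ± 27.8 to 2.38 ± 1.44 (log2 −5.70, SE 0.37, adjusted p = 4.73e-06). Col1a1 (chromosome 11, 94936224 to 94953042), for the main chain of type I collagen, fell from 87.8 ± 1.54 to 17.6 ± 1.48 (log2 −2.31, SE 0.22, adjusted p = 7.71e-05).

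By limma 7242 of 13610 genes differed, 3717 higher and 3525 lower on polysomes. Scaling to the summed FPKM of protein-coding genes moved the median log2 of all genes from 0.02 to −0.20. The split became 2480 higher and 4534 lower, so directions near this shift depend on the scaling. The count was 4077 without cHet replicate 1, 4744 without cHet replicate 2 and 4631 without cHet replicate 3, and 9658 without the 2 libraries that stood apart. Besides Ndufb3, large increases were seen for Lsm7 (43.0 ± 1.31 to 136 ± 11.7) and Nop10 (67.2 ± 2.27 to 205 ± 9.89), which act in mRNA decay and ribosome biogenesis, and for Selenom, Dbi, Ppbp, Tmsb15b1, Hist1h2ag and Hist1h2ah. Hist1h2ah, whose reads near-identical histone genes share, lost its call without cHet replicate 3 (log2 1.71 with it and 1.51 without). The largest decreases among protein-coding genes outside the mitochondrial genome were in Gpc3 (259 ± 18.2 to 46.0 ± 4.35, log2 −2.49, SE 0.37) and Eno1b (−2.39). Gpc3 is a proteoglycan gene of growth control. Eno1b is a copy of an enolase gene, and its reads may not be separable from those of its parent, which was not tested. Gdf5 was higher on polysomes (log2 0.65, SE 0.19, adjusted p = 0.0148), a call lost without cHet replicate 1 (adjusted p = 0.0671) or replicate 2 (0.0734), and with protein-coding scaling (log2 0.42). Runx3 was higher as well (0.60, SE 0.22, adjusted p = 0.0379), but not with the lysate as a block (adjusted p = 0.0584), without any of the cHet replicates (adjusted p = 0.217, 0.163 and 0.0814) or with protein-coding scaling (log2 0.39). Mettl14 (−0.43, adjusted p = 0.173) and Runx2 (−0.27, adjusted p = 0.230) did not pass. Mettl14 passed without cKO replicate 3 (adjusted p = 0.00525), which enters only through the shared spread, and Runx2 with protein-coding scaling (log2 −0.49, adjusted p = 0.0472).

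Among nuclear genes of oxidative phosphorylation, 73 of 94 rose and 8 fell on cHet polysomes, with a median log2 of 1.01 (camera adjusted p = 2.19e-12; adjusted p = 0.576 with an estimated correlation). Adjusted over the list alone, 75 rose and 9 fell. Cox6b1 rose from 205 ± 9.75 to 593 ± 25.4 FPKM, and Ndufs4 from 25.9 ± 0.822 to 57.4 ± 3.38. Of 13 RNAs encoded in the mitochondrial genome 12 fell, over all genes and over the list alone, with a median of −3.35 (camera adjusted p = 4.37e-07; adjusted p = 0.576 with an estimated correlation). Of 29 collagens 28 fell by either count, with a median of −1.81 (camera adjusted p = 1.33e-12; adjusted p = 0.576 with an estimated correlation). Col4a1 of basement membranes fell by 2.26 on the log2 scale and Col5a2 by 1.87. Of 51 histone genes 32 rose and 0 fell (33 and 1 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 5.41e-06; adjusted p = 0.585 with an estimated correlation). Hist3h2ba rose from 30.4 ± 4.61 to 86.7 ± 11.3. Without cHet replicate 1 or 3 only 10 and 9 histone genes rose over all genes.

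Translation factors fell in 21 and rose in 4 of 32 cases, by either count, with a median log2 of −0.80 (camera adjusted p = 2.17e-04; adjusted p = 0.372 with an estimated correlation). Pabpc1, the poly(A)-binding protein gene, fell from 192 ± 6.16 to 61.0 ± 3.70 FPKM and Eef1a1, for the elongation factor that delivers tRNAs, from 4810 ± 78.2 to 1565 ± 128. Of 78 ribosomal protein genes 28 fell and 5 rose (26 and 5 adjusted over the list alone), with a median of −0.33 (camera adjusted p = 9.63e-04; adjusted p = 0.770 with an estimated correlation). Rplp0 fell from 1953 ± 89.6 to 624 ± 78.1. Of 25 cell cycle genes 13 fell and 1 rose, by either count, with a median of −0.63 (camera adjusted p = 7.34e-04; adjusted p = 0.576 with an estimated correlation). The helicase subunit genes Mcm3 and Mcm5 fell by 1.57 and 1.64 on the log2 scale. Cartilage matrix genes fell in 10 of 14 cases, and adjusted over the list alone 10 fell and 1 rose, with a median of −1.25 (camera adjusted p = 0.00197; adjusted p = 0.576 with an estimated correlation). Col2a1, the main cartilage collagen gene, fell from 23.1 ± 3.89 to 6.41 ± 0.768.

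Smaller groups followed. Of 15 epidermis genes 12 fell and 1 rose, by either count (median log2 −0.80, camera adjusted p = 7.42e-04; adjusted p = 0.576 with an estimated correlation), with Krt5 going from 91.6 ± 2.19 to 30.5 ± 2.78 FPKM. Of 11 tendon genes 7 fell by either count (median −0.88, camera adjusted p = 0.0111; adjusted p = 0.576 with an estimated correlation), led by the matrix gene Tnc, which fell by 2.27 on the log2 scale. Of the 18 genes of the m6A machinery 8 fell and 1 rose, by either count (median −0.59, camera adjusted p = 0.0236; adjusted p = 0.576 with an estimated correlation). The writer subunit gene Virma fell by 1.01 on the log2 scale and the demethylase gene Alkbh5 rose by 0.84. Of 33 Hox genes 10 rose and 1 fell (6 and 0 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.0329; adjusted p = 0.731 with an estimated correlation). Hoxd13 rose from 244 ± 40.2 to 428 ± 59.0. The Hox call was lost without cHet replicate 1 (median 0.37, adjusted p = 0.0610) or cHet replicate 2 (0.38, adjusted p = 0.0532), and the Hox and m6A machinery calls with length and GC trends removed (0.22, adjusted p = 0.341, and −0.39, adjusted p = 0.153). The GDF5 and BMP genes did not pass as a group (28 tested, median 0.18, camera adjusted p = 0.249), and 9 of them rose and 3 fell, by either count. The background for such counts is that 3717 of all 13610 genes rose and 3525 fell. Id2, for an inhibitor of differentiation, rose from 59.2 ± 3.99 to 129 ± 13.3 and Msx1, a homeobox gene of undifferentiated mesenchyme, from 84.0 ± 14.2 to 185 ± 18.8.

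**Figure D3:**
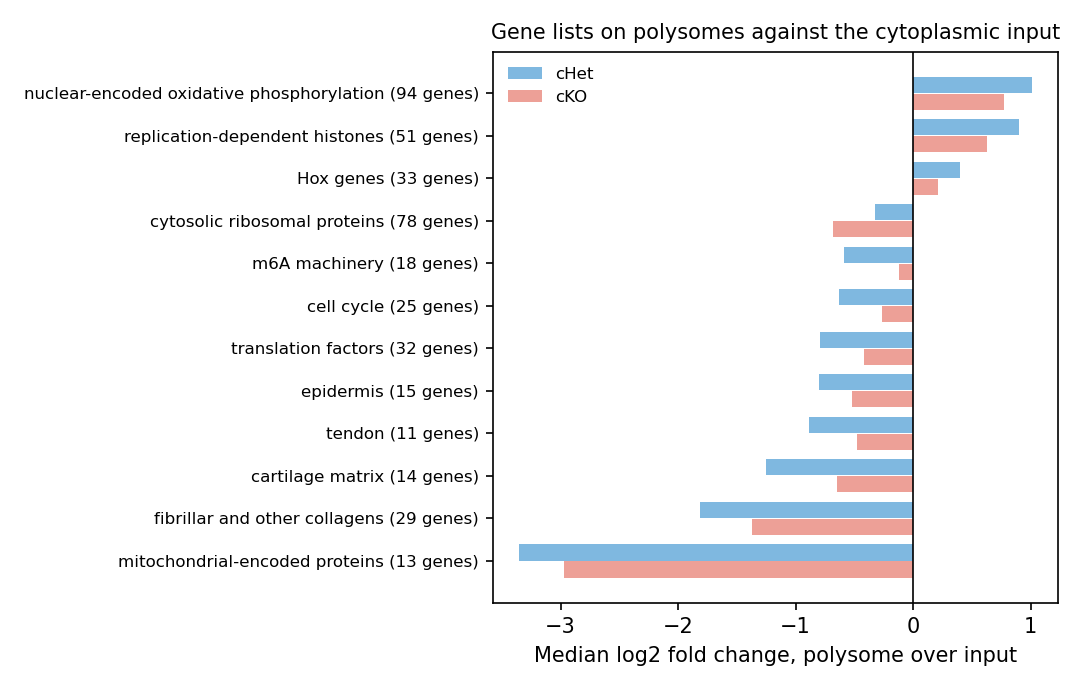
Bars give the median log2 fold change between polysome and input RNA over the genes of each of 12 groups, in cHet (blue) and cKO (red) limb buds. Genes of oxidative phosphorylation have medians of 1.01 in cHet and 0.77 in cKO, collagens −1.81 and −1.37, and mitochondrially encoded genes −3.35 and −2.97.

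The same comparison was made in knockout limb buds. Respiratory chain and histone mRNAs were enriched on cKO polysomes, and mitochondrially encoded, collagen and ribosomal protein RNAs were depleted. Here too none of these groups passed with an estimated correlation (adjusted p = 0.409 to 0.648). Ndufb3 rose from 46.8 ± 5.30 FPKM in cKO input to 132 ± 20.1 on cKO polysomes (SD, n = 3 each; log2 1.48, SE 0.14, adjusted p = 9.37e-05). Rplp0, for a protein of the ribosomal stalk, fell from 2439 ± 518 to 584 ± 60.5 (log2 −2.05, SE 0.16, adjusted p = 2.53e-05). Col4a1 fell from 29.7 ± 6.31 to 8.07 ± 3.29 (log2 −1.92, SE 0.24, adjusted p = 3.93e-04).

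By limma 4424 of 13610 genes differed, 2306 higher and 2118 lower on polysomes. With protein-coding scaling the median of all genes went from 0.06 to −0.06 and the split to 1684 higher and 2672 lower. The count was 1800 without cKO replicate 2, and 8012 without the 2 libraries that stood apart. Among the largest increases of protein-coding genes with an FPKM of at least 5 on polysomes, Dbi (log2 1.63), Snapc5 (1.51) and Lsm7 (1.47) moved by less than 1.5 times without any replicate. Tceal9 (1.71), Pmaip1 (1.70) and Uqcrb (1.62) had 1.12, 0.97 and 1.07 without cKO replicate 3, still past the threshold, and Sumo2 (1.85) lost its call without cKO replicate 2 or replicate 3 (1.73 and 1.17). By this measure the largest increase was that of Gapdh (log2 3.37, SE 0.78), from 1.86 ± 0.606 to 21.1 ± 10.2 FPKM. These levels are low for a glycolytic housekeeping gene with many processed pseudogenes, so its values are uncertain. Gdf5 was higher on cKO polysomes (log2 0.67, SE 0.19, adjusted p = 0.0212), but not without cKO replicate 2 (adjusted p = 0.10), without the 2 libraries that stood apart (log2 0.50, adjusted p = 0.0537) or with protein-coding scaling (log2 0.54). Mettl14 (0.38, adjusted p = 0.273), Runx2 (−0.36, adjusted p = 0.155) and Runx3 (−0.14, adjusted p = 0.661) did not pass. The direction of Mettl14 turned without cKO replicate 3 (−0.08) and that of Runx3 without cKO replicate 1 (0.14).

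Of 94 nuclear genes of oxidative phosphorylation 66 rose and 4 fell (70 and 6 adjusted over the list alone; median log2 0.77, camera adjusted p = 3.53e-14; adjusted p = 0.409 with an estimated correlation). Of 13 mitochondrially encoded RNAs 12 fell (13 adjusted over the list alone; median −2.97, camera adjusted p = 1.09e-11; adjusted p = 0.409 with an estimated correlation), with mt-Co3 at 118 ± 27.6 and 2.24 ± 0.810 FPKM. Of 29 collagens 25 fell (27 adjusted over the list alone; median −1.37, camera adjusted p = 6.52e-15; adjusted p = 0.409 with an estimated correlation). Ribosomal protein genes fell in 55 of 78 cases (59 adjusted over the list alone; median −0.68, camera adjusted p = 2.52e-19; adjusted p = 0.452 with an estimated correlation). Of 51 histone genes 13 rose (10 adjusted over the list alone; median 0.63, camera adjusted p = 2.40e-05; adjusted p = 0.648 with an estimated correlation), among them Hist1h4i (log2 1.41). Over all genes 24 histone genes rose without cKO replicate 1 and 4 and 7 without cKO replicates 2 and 3. Translation factors fell in 15 and rose in 3 of 32 cases (16 and 3 adjusted over the list alone; median −0.42, camera adjusted p = 1.77e-04; adjusted p = 0.369 with an estimated correlation), with Pabpc1 falling by 1.52 on the log2 scale. Without cKO replicate 1 the median of translation factors was −0.63.

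Cartilage matrix and tendon genes fell in 4 of 14 and 4 of 11 cases, by either count, with medians of −0.65 and −0.48 (camera adjusted p = 0.00860 and 0.0154; adjusted p = 0.648 and adjusted p = 0.452 with an estimated correlation). Without cKO replicate 1 the cartilage matrix median was −1.13. Col2a1 fell from 30.7 ± 5.92 to 11.2 ± 6.78 FPKM and Tnc by 1.76 on the log2 scale. Of 15 epidermis genes 7 fell and 1 rose, by either count (median −0.52, camera adjusted p = 0.00860; adjusted p = 0.648 with an estimated correlation), a call lost without cKO replicate 3 (−0.39, adjusted p = 0.204). Of 25 cell cycle genes 8 fell and 1, Birc5, rose, by either count (median −0.27, camera adjusted p = 0.0410; adjusted p = 0.731 with an estimated correlation). The cell cycle call was lost without cKO replicate 2 (−0.11, adjusted p = 0.247) or replicate 3 (−0.30, adjusted p = 0.0749), and with the lysate as a block (adjusted p = 0.0611), and the median was −0.43 without cKO replicate 1. Bub1b, a spindle checkpoint gene, fell by 0.84 on the log2 scale. Of 28 GDF5 and BMP genes 8 rose and 0 fell, by either count (median 0.26, camera adjusted p = 0.0916), where 2306 of all 13610 genes rose and 2118 fell. Among the 8 were Id2 (log2 0.86) and Msx1 (0.76), the latter not without cKO replicate 2 (adjusted p = 0.0653).

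The last comparison asked whether the genotype changed the polysome to input ratio of a gene. As groups, ribosomal protein mRNAs had a lower ratio in cKO than in cHet, and cell cycle, collagen and m6A machinery mRNAs a higher one, but no call held with an estimated correlation (adjusted p = 0.776 each). The collagen median was 0.02 without cKO replicate 1 (adjusted p = 0.625), and the m6A machinery call was lost without both libraries that stood apart (adjusted p = 0.160). Mcm4, a subunit gene of the replicative helicase, went from 41.8 ± 3.54 to 16.1 ± 0.647 FPKM between input and polysomes in cHet, and from 30.4 ± 9.43 to 23.3 ± 4.78 in cKO (SD, n = 3 each; interaction log2 1.01, SE 0.30). Tnrc6c, which acts in microRNA silencing, went from 7.10 ± 0.463 to 4.01 ± 0.232 in cHet and from 6.73 ± 0.445 to 6.40 ± 0.430 in cKO (0.74, SE 0.17). Rpl28, a ribosomal protein gene, went from 532 ± 36.8 to 487 ± 19.3 in cHet and from 580 ± 70.7 to 342 ± 61.6 in cKO (−0.65, SE 0.22).

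No single gene passed. By limma the ratio changed for 0 of 13610 genes, with a lowest adjusted p of 0.790, and 638 had an unadjusted p under 0.05. By voom it was 0 and 613, and leaving out any replicate also gave 0. Protein-coding scaling moved the median interaction of all genes from 0.02 to 0.12. Gnl2 (0.89), Tpx2 (0.82), Ing3 (0.83) and Gapdh (4.82, uncertain as above) were the other higher genes with the smallest p, and Stfa3 (−1.68), Brd3os (−0.73), Emp2 (−0.63) and Sema4g (−0.55) the other lower ones. The interaction was 0.02 for Gdf5 (SE 0.27, adjusted p = 0.985), −0.09 for Runx2 (SE 0.26, adjusted p = 0.921) and −0.74 for Runx3 (SE 0.32, adjusted p = 0.790). For Mettl14 it was 0.82 (SE 0.37, adjusted p = 0.790) and for Runx1 0.03 (SE 0.28, adjusted p = 0.977). Single lysates moved 2 of these, as Mettl14 was at 0.35 without cKO replicate 3 and Runx3 at −0.46 without cKO replicate 1.

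Of 78 ribosomal protein genes 72 had a lower ratio in cKO, with a median log2 of −0.42 (camera adjusted p = 7.19e-20; adjusted p = 0.776 with an estimated correlation). Of 25 cell cycle genes 23 had a higher ratio, with a median of 0.46 (camera adjusted p = 4.18e-06; adjusted p = 0.776 with an estimated correlation), and of the 18 genes of the m6A machinery 16, with a median of 0.33 (camera adjusted p = 0.00353; adjusted p = 0.776 with an estimated correlation). These 3 calls held without any 1 of the replicates, although without cKO replicate 1 the cell cycle median was 0.19 (adjusted p = 0.00460). Without both libraries that stood apart, those of ribosomal proteins (−0.18, adjusted p = 2.38e-08) and cell cycle genes (0.32, adjusted p = 8.20e-06) held and that of the m6A machinery did not (0.06, adjusted p = 0.160). The latter was also lost with length and GC trends removed (0.15, adjusted p = 0.0648). Of 29 collagens 28 had a higher ratio, with a median of 0.39 (camera adjusted p = 1.02e-04; adjusted p = 0.776 with an estimated correlation), but without cKO replicate 1 the median was 0.02 (adjusted p = 0.625), without cKO replicate 3 it was 0.62, and without both libraries that stood apart it was 0.20 (adjusted p = 0.00632). In each of these lists 0 members passed over all genes or adjusted over the list alone.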

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

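The tests of carry-over, of the genotype for the 2 libraries that stood apart and of gene length as a main source were chosen only after the result was seen, as were the fits without both libraries and with length and GC trends removed.

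A difference between the genotypes in the polysome to input ratio, tested as an interaction, singles out 9 gene groups. The median log2 interaction was −0.42 for ribosomal proteins (72 of 78 genes lower in cKO, camera adjusted p = 7.19e-20), 0.46 for cell cycle genes (23 of 25 higher, 4.18e-06), 0.39 for collagens (28 of 29 higher, 1.02e-04) and 0.33 for the m6A machinery (16 of 18 higher, 0.00353). It was 0.36 for epidermis genes (14 of 15 higher, adjusted p = 0.00353), 0.59 for cartilage matrix genes (11 of 14 higher, 0.0223), −0.17 for nuclear genes of oxidative phosphorylation (74 of 94 lower, 0.00332), −0.22 for replication-dependent histones (38 of 51 lower, 0.0138) and −0.21 for Hox genes (26 of 33 lower, 0.0222). With an estimated correlation none passed, at an adjusted p of 0.900 for histones and 0.776 for each of the other 8 groups.

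Several of these calls rested on single libraries. Without cKO replicate 1, cartilage matrix (median 0.26, adjusted p = 0.411), epidermis (0.05, 0.465), oxidative phosphorylation (−0.11, 0.0767), histones (−0.20, 0.0923), Hox genes (−0.13, 0.360) and collagens (0.02, 0.625) did not pass. The same held for cartilage matrix without cKO replicate 2 (0.54, adjusted p = 0.0527), histones without cHet replicate 3 (−0.07, 0.588) and Hox genes without cHet replicate 1 (−0.16, 0.0565). Calls were kept at medians that moved by over 1.5 times for cell cycle genes without cKO replicate 1 (0.19), epidermis (0.58) and collagens (0.62) without cKO replicate 3, and histones without cHet replicate 2 (−0.37). Without both libraries that stood apart, ribosomal proteins (−0.18, adjusted p = 2.38e-08), cell cycle (0.32, 8.20e-06), collagens (0.20, 0.00632) and epidermis (0.15, 0.0377) passed. Those of the m6A machinery (0.06, adjusted p = 0.160), cartilage matrix (0.08, 0.894), oxidative phosphorylation (0.03, 0.476), histones (0.06, 0.894) and Hox genes (−0.03, 0.894) did not, and the medians of oxidative phosphorylation and histones changed sign. With length and GC trends removed, the m6A machinery (0.15, adjusted p = 0.0648), oxidative phosphorylation (−0.09, 0.508), histones (0.09, 0.664) and Hox genes (−0.13, 0.260) did not pass. Protein-coding scaling ended the call of cartilage matrix (adjusted p = 0.0536) and quantile normalization that of oxidative phosphorylation (−0.07, adjusted p = 0.566).

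The input library cKO replicate 3 stood apart from the other input libraries. The genotype is argued against as the source of its trend with GC content, which the other cKO input libraries did not share. The higher of their rank correlations of GC with the difference from the cHet mean was −0.0175, against 0.680 in this library. For the rest of its deviation the genotype cannot be told apart from other differences between libraries. On the second principal component the other cKO input libraries lay at 2.56 and 10.3, between cHet input (19.4 to 19.8) and this library (−61.9). This library also had the lowest Mettl14 value, at 1.26 FPKM against 2.60 and 3.32 in the other cKO input libraries. A GC trend of this library is a candidate explanation, because removing the trend of each library lowered the SD of its deviation over 11534 genes by 34.7%, from 0.708 to 0.462, which still exceeded the 0.186 to 0.346 of the other input libraries. Its rank correlation with GC was 0.711, where the other input libraries had −0.222 to −0.118. A gene length trend is argued against as the main source, since its removal lowered the SD by 5.66% and the variance by 11%, and stays open only as a small part, as 5.66% lay between the bounds set for and against any part.

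The library cKO polysome replicate 1 lay between the input and the other polysome libraries, with a score of 0.505 on an axis from 0 at the cHet input mean to 1 at the cHet polysome mean over 13443 genes. Carry-over of all RNA that is not on polysomes alike is argued against: mitochondrial reads put the input share of this library at −0.148, and the 61 shortest of 508 other depleted RNAs at −0.00678, where all 508 gave 0.476 and the 3 longer classes of gene models 0.731, 0.645 and 0.437. A gene length trend is argued against as well, since the score was 0.499 after its removal, while carry-over of longer RNAs alone was not tested. The genotype cannot be told apart from other differences between libraries. The other cKO polysome libraries scored 0.934 and 0.825, below the 0.975 to 1.03 of the cHet polysome libraries but far from this library. The axis was drawn through the cHet means, so the cHet polysome scores average 1 by construction. Libraries not used to draw it may score lower for that reason alone. The genotype stays open because 3 libraries per genotype do not separate a spread within cKO from an effect of the knockout.

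The 6 libraries compared, or for the ratio the 6 lysates with both their libraries, can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05. Where input and polysomes were compared, the 6 libraries of the other genotype stayed as they were in the fit of all 12. In the genotype comparisons the real split called 0 genes by limma, in input (highest other split 1 gene, 1943 genes with an unadjusted p under 0.05, 0 by voom), on polysomes (highest other 0, 2743, 0 by voom) and for the ratio (highest other 0, 638, 0 by voom), so all 10 splits called as many. No split can call fewer than 0 genes, so this count could not have come out otherwise and decides nothing. At an unadjusted p under 0.05 the highest other split had 286 genes in input, 996 on polysomes and 497 for the ratio. For cHet polysome against input the real split called 7242 genes and the highest other 1, and for cKO polysome against input 4424 and 893, so 1 of the 10 splits, the real one, called as many in each. Every other split puts input and polysome libraries into the same group, so their lower counts follow largely from the design. The 893 genes came from the split that puts cKO polysome replicate 1 with cKO input replicates 1 and 2, which exchanges the 2 libraries that stood apart and points to a structure of the samples.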

How the results depend on the processing

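Chosen only after the results were seen were the tests with length trends, or length and GC trends, removed, with library quality weights, and without the 2 libraries that stood apart. Depth limits low genes most in cHet polysome replicate 2, where 1 read in a gene of 1 kb was worth 0.0930 FPKM at 10349912 reads, a floor that covers counting error only.

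In input, where 0 genes changed by limma (1943 at an unadjusted p under 0.05, 0 by voom), a fit of all 12 libraries gave 82, of which 70 were among the 326 found without cKO input replicate 3. Removing length and GC trends gave 55, of which 54 were among the 326, and library quality weights gave 1084, which held 321 of them. On polysomes, from 0 (2743 at an unadjusted p under 0.05, 0 by voom), all 12 libraries gave 184, of which 101 were among the 160 found without cKO polysome replicate 1, and quality weights gave 2621, which held all 160. These weights were 0.0616 for cKO input replicate 3 and 0.155 for cKO polysome replicate 1. The weighted fits thus come close to leaving out the same libraries, so the shared calls are not separate evidence. On polysomes cHet replicate 1 had a weight of 6.77, against 0.871 and 0.842 in cHet replicates 2 and 3. Quality weights also gave 11107 genes for cHet polysome against input, 8840 for cKO polysome against input and 13 for the ratio. A log2 change of at least 1 left 2318 and 880 genes in the cHet and cKO comparisons of fractions, fewer by construction. Without the 2 libraries that stood apart, cKO polysome against input had 8012 genes and 75 genes changed in both fractions. The ratio, with 0 genes (638 at an unadjusted p under 0.05, 0 by voom), had 1 at a pseudocount of 0.01 and 7 with no filter on low values. Except for the minimum change, the cause was not tested.

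Leaving out 1 library gave 0 to 326 genes in input, above 0 only without cKO input replicate 2 (47) or 3 (326), and 0 to 231 on polysomes, above 0 without cHet polysome replicate 1 (1) and cKO polysome replicates 1 (160) and 2 (231). Of these 231, 78 were among the 160, and of the 47, 34 were among the 326. Leaving out 1 lysate gave 4077 to 8949 genes in cHet polysome against input, with 4077 to 4744 where a cHet lysate was left out, and 1800 to 5861 in cKO polysome against input, with 1800 without cKO replicate 2. For the ratio it gave 0 each time. Fewer samples are part of these settings, and the cause was not tested further.

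With the replicate number as a block between the genotypes, polysomes had 42 genes (31 higher, 11 lower, 32 among the 160) and input 0. Libraries of the 2 genotypes share only a number, since their deviations correlated at −0.35 to 0.22 and 2 of 12 libraries correlated best with their own number, so this pairing is not supported by the values. With the lysate as a block, which pairs input and polysome RNA, 7425 genes changed in cHet, 4479 in cKO and 0 in the ratio.

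Of the gene groups, 7 passed camera in input, 11 on polysomes, 12 in cHet and 10 in cKO polysome against input and 9 for the ratio. With an estimated correlation it was 0 in each of the 5. By fry, which asks whether a group's genes move one way and compares with no other genes, it was 0 in input, 0 on polysomes and 0 for the ratio, while 11 of the 12 passed in cHet and 6 of the 10 in cKO polysome against input. Without the libraries that stood apart, 6 groups passed on polysomes, 5 of them among the 11, and 5 for the ratio, 4 of them among the 9. Gained were limb patterning genes on polysomes (adjusted p = 0.836 with an estimated correlation) and GDF5 and BMP genes in the ratio, whose median went from 0.03 to −0.11 (adjusted p = 0.0377; adjusted p = 0.873 with an estimated correlation). In input 8 passed, 4 of them among the 7, with GDF5 and BMP, oxidative phosphorylation, mitochondrially encoded and endothelium genes gained (adjusted p = 0.710 to 0.717 with an estimated correlation). With length and GC trends removed 7 groups passed on polysomes and 5 for the ratio, all among the 11 and the 9, and 10 of the 12 passed in cHet polysome against input. The interaction medians of oxidative phosphorylation (0.030) and histones (0.057) reversed without both libraries, and that of histones (0.087) with length and GC trends removed. The cause was not tested.

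The genes whose direction reversed had not passed the threshold, and the cause was not tested. With protein-coding scaling these were Mettl14 on polysomes (0.027), Runx1 in cHet polysome against input (−0.071) and Runx2 in the ratio (0.010), and with quantile normalization Gdf5 (−0.041) and Runx1 (−0.035) in the ratio. With length trends removed, Runx2 was at 0.10 in cHet polysome against input and Runx1 at −0.15 in the ratio. With length and GC trends removed, Runx1 was at 0.10 in input and −0.23 in the ratio, Runx2 at 0.10 in cHet and Runx3 at 0.016 in cKO polysome against input. With quality weights, Mettl14 was at 0.013 on polysomes and −0.13 in cKO polysome against input, Runx3 at 0.13 in the latter and Id2 at 0.046 in the ratio. Without the 2 libraries that stood apart, Runx3 was at 0.0052 in cKO polysome against input and Gdf5 at −0.14 in the ratio. Leaving out 1 replicate gave ranges of both signs for Gdf5 (−0.014 to 0.089) and Runx1 (−0.12 to 0.24) in the ratio, Mettl14 on polysomes (−0.097 to 0.032) and, in cKO polysome against input, Mettl14 (−0.081 to 0.69) and Runx3 (−0.33 to 0.14).

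For the other gene and group values, direction and side of the threshold were the same for all 340 compared with a pseudocount of 1. They were the same for all 291 compared at 0.01, with voom weights and with robust empirical Bayes each, and for all 218 with a filter at 5. The numbers compared differ because group values entered only some settings and the filter leaves fewer genes. They were the same for 339 with median-ratio scaling (1 lost its call), 288 with no filter (3 lost), 286 with quantile normalization (3 lost) and 282 with protein-coding scaling (5 lost, 1 gained).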

Other observations

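The tests of length, GC and level trends, genomic DNA, exon junctions on polysomes and methylation motifs were chosen only after the result was seen.

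Erythroid genes were lower in cKO in both fractions, in 12 of 12 genes of input RNA (median log2 −0.51, camera adjusted p = 0.0643; adjusted p = 0.853 with an estimated correlation) and in 11 of 11 of polysome RNA (−0.40, camera adjusted p = 0.0741; adjusted p = 0.834 with an estimated correlation). Neither passed, and for 0 of these genes were the genotype groups apart, where chance gives 10% for a single gene. These genes varied together too, at an estimated correlation of 0.810 in input and 0.734 on polysomes. The input list passed with the replicate number as a block (adjusted p = 0.0189) and with length and GC trends removed (adjusted p = 0.0223). On polysomes it passed with that block (adjusted p = 0.0138) and not without cKO polysome replicate 1, where the median turned to 0.05 (adjusted p = 0.866) while camera kept its lower direction. Tendon genes were lower in cKO input in 8 of 11 cases (median −0.36, camera adjusted p = 0.0655; 0.0433 with the block and 0.0223 with the trends removed) and in 6 of 10 on polysomes (−0.01, camera adjusted p = 0.942). Of 16 p53 target genes, 8 rose and 1 fell on cHet polysomes against input (median 0.46, camera adjusted p = 0.195), and 4 rose on cKO polysomes (0.41, camera adjusted p = 0.142).

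Genes with few exon junctions were higher in cKO input. Over 11517 genes, the median log2 difference between cKO and cHet input was 0.13 for genes of 1 exon, 0.21 for 2 exons and 0.16 for 3, against −0.09 for 13 to 20 exons and −0.13 above 20. The library that stood apart, cKO input replicate 3, had the largest differences. In cKO input replicates 1 to 3 they were 0.08, 0.04 and 0.27 for 1 exon, 0.25, 0.12 and 0.35 for 2 exons, and −0.09, −0.03 and −0.12 above 20. Trends with gene length, GC content and mean level are argued against as the whole cause, since with these regressed out the rank correlation of exon junctions per kb with the difference went from −0.170 to −0.280, where the highest size in the other 9 splits of the 6 libraries was 0.234 before and 0.265 after, so the real split was the highest only after. For each library the correlation was also taken with its deviation from the median of the other input libraries. That median mixes both genotypes, so opposite signs in the genotypes partly follow from how these values were computed. With length, GC content and mean level regressed out, they were −0.284, −0.201 and −0.212 in cKO input replicates 1 to 3. In cHet input they were 0.221, 0.136 and 0.269. Before that they were −0.309, −0.213 and −0.0283 in cKO input and 0.194, 0.0935 and 0.248 in cHet input. All were taken across genes, which are not independent replicates. Genomic DNA reads are argued against too, as 1093 olfactory receptor genes averaged 7.68e-04 FPKM in cKO input, within the 6.63e-04 to 9.89e-04 of the cHet input libraries.

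The complex that holds METTL14 methylates RNA away from exon junctions, so its loss may act on RNAs with few junctions. On polysomes, over 11408 genes, the same correlation with the genotype difference was 0.0210 (highest size in the other splits 0.241). For the deviation of a library from the median of the other polysome libraries, it was 0.125, −0.0613 and −0.131 in cKO polysome replicates 1 to 3. The number of methylation motifs per kb had a correlation of −0.0538 with the input difference (highest size in the other splits 0.0749). Both stay open, and an effect of the knockout cannot be told apart from another difference between the groups, because the cKO polysome libraries went both ways and 10 splits are too few for a share under 0.05.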
